A study of Mus musculus with 34 samples.

How the data were processed

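RNA of mouse liver was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample and 34 arrays in all. The mice were C57/B6 wild-type animals or animals with a Pdgf-c transgene (platelet-derived growth factor C). Some transgenic mice ate a diet with 0.06% peretinoin, an acyclic retinoid, from weaning at week 4; the others ate the basal diet. Livers were sampled at week 20 or week 48, and at week 48 tumours were sampled as well. Per the labels' protocols, total RNA was extracted with an RNeasy kit and labelled as biotinylated cRNA.

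The deposited values are signal intensities on a linear scale. They were made with MAS5, per the submitters' processing notes, which give no version. Every value was positive with 1 decimal, and the 2% trimmed mean of each of the 34 arrays lay between 500.003 and 500.004. The array held 45101 probe sets, of which 64 were controls. The platform's probe table paired 34945 probe sets with exactly 1 gene symbol, 932 with several and 9160 with none. Of the probe sets with 1 symbol, 34754 had an Entrez ID in the RefSeq gene table, and 0 symbols were updated through it. They stood for 18193 genes. No coordinates were used. The number of arrays per group limits the precision, since the files hold no counts.

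Each signal was taken as log2(signal + 16). Of the probe sets other than controls, the 60% with the highest mean signal over all arrays were kept. For each gene the kept probe set with exactly 1 symbol and the highest mean signal stood for the gene, which left 13099 genes. A single model with 7 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that all groups shared 1 estimate of the spread. The 5 main comparisons were transgenic against wild-type liver at each age, tumour against transgenic liver at week 48, and peretinoin against basal diet in transgenic mice at each age. The 4 other comparisons were week 48 against week 20 in wild-type and in transgenic mice, and the difference between ages of the transgene effect and of the peretinoin effect. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each comparison. Errors of log2 changes are moderated standard errors, and errors of signals are SD. Chance alone would put 655 of the 13099 genes under an unadjusted p of 0.05.

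Gene lists were written from general knowledge before the data were examined: 22 pathway lists and 13 lists of cell type or tissue markers. Each was tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 35 lists. Members were also counted with p adjusted over the list alone. The named genes followed a rule fixed at the same time. It took a panel of 15 genes, then per main comparison the 5 largest rises and the 5 largest falls among called genes whose groups did not overlap, leaving out clones and Gm, Rik and LOC genes. From each list it took the 2 to 4 members of smallest p, and from each difference between ages the 5 genes of smallest p. Other members of a list are named where a sentence about the list needs them.

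A transgene signature score compared the diets without using the same arrays on both sides. For each age, the genes called with at least a 1.5-fold change in a fit of the other age's wild-type and transgenic arrays alone were used. The score of an array was the mean log2 signal of the genes that rose minus that of the genes that fell. Peretinoin and basal diet were compared with a two-sided exact permutation test over the 252 assignments of 10 arrays, whose smallest possible p is 0.00794.

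The quality of each array was read from the ratio of 3' to 5' probe sets of Actb and Gapdh, the correlation with the rest of its group, and the means of the skeletal muscle and pancreatic acinar lists. An array counted as carrying another tissue's transcripts when either mean lay 3 or more log2 units above the median of all arrays. No array was left out of the main results. No duplicated array was found: the highest correlation of log2 signals between 2 arrays was 0.982, and that pair had identical signals in 0.293% of probe sets.

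The scripts were tested on simulated arrays drawn from the real mean and residual spread of each gene, independently between genes, with 200 genes changed by 1.5, 2 or 4-fold. In the simulated week 20 transgenic comparison 37.3%, 76.1% and 97.0% of them were called, with 5 unchanged genes among 145 calls. In the tumour comparison the shares were 46.3%, 76.1% and 98.5%, with 8 unchanged genes among 155 calls. In the week 20 peretinoin comparison they were 49.3%, 68.7% and 95.5%, with 7 among 150. In the difference of the transgene effect between ages they were 11.9%, 52.2% and 93.9%, with 3 among 108. A list raised on purpose in the simulated week 20 transgenic comparison was called at adjusted p = 0.000111, and at adjusted p = 0.000759 with an estimated correlation. It was missed in the difference of the transgene effect (adjusted p = 0.072, and 0.0758 with an estimated correlation). With an estimated correlation it was also missed in the week 48 transgenic comparison (0.0969) and in the difference of the peretinoin effect (0.0839), where 2 and 1 lists that had not been raised were called at the preset correlation.

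The alternatives fixed before the data were examined were log2(signal + 1), log2(signal + 64), no signal filter, the upper 40% of probe sets and quantile normalisation. They also included median centring, averaging a gene's probe sets, each probe set on its own, a fit of the compared arrays alone and the replicate number as a block. The others fixed then were array weights, eBayes without the trend, a minimum of 1.5-fold, leaving out each array in turn, the estimated correlation for lists, and a signature with no fold minimum. Alternatives chosen after seeing the data were a fit without the 6 arrays that carried muscle or pancreas transcripts, the log2 Actb 3'/5' ratio as a covariate, and the first 2 components of the clock list as covariates (75.0% and 14.1% of the variance of its 12 genes).

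Among 154 named genes with several probe sets, 8 pairs of gene and comparison had another probe set that passed the test against the direction of the reported one: Uroc1 and Cd8a in the week 20 transgenic comparison, Cd8a in the week 48 one, Hnf4a, Tcn2 and Thbs2 with peretinoin at week 20, Upk1b with age in wild-type mice and Smad2 with age in transgenic mice. Probe sets without exactly 1 symbol were left out of the comparisons.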

Results

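Liver RNA of 34 samples was profiled in 7 groups. At week 20 there were 5 wild-type livers, 5 livers of Pdgf-c transgenic mice on the basal diet and 5 livers of transgenic mice on the peretinoin diet. At week 48 there were 4 wild-type livers, 5 transgenic livers on the basal diet, 5 transgenic livers on the peretinoin diet and 5 tumours from transgenic mice. Per the labels, week 20 stands for fibrosis in this model and week 48 for tumours. The median signal of an array ranged from 71.5 to 95.7 at a common trimmed mean, and the number of arrays limits the precision.

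Pdgfc, the gene of the transgene, gave a mean signal of 336 ± 56.5 (SD, n = 5, range 258.9 to 411.7) in wild-type liver at week 20 and 316 ± 72.1 (n = 5, 210 to 386.3) in transgenic liver. At week 48 the means were 482 ± 26.4 (n = 4, 458.2 to 518.9) and 798 ± 277 (n = 5, 517.2 to 1218.8). With peretinoin they were 474 ± 172 (n = 5, 346.7 to 744.2) at week 20 and 603 ± 56.0 (n = 5, 506.4 to 646.5) at week 48, and in tumours 796 ± 160 (n = 5, 613.2 to 1015.1). Whether the Pdgfc probe sets cover the transgene is not given, so these values do not check the genotype labels. The log2 change of Pdgfc with the transgene was -0.10 ± 0.20 at week 20 (adjusted p = 0.757). At week 48 Pdgfc rose by 0.65 ± 0.21 (adjusted p = 0.0272), a call that quantile normalisation, averaged probe sets and a fit of the compared arrays alone each ended.

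**Figure D1:**
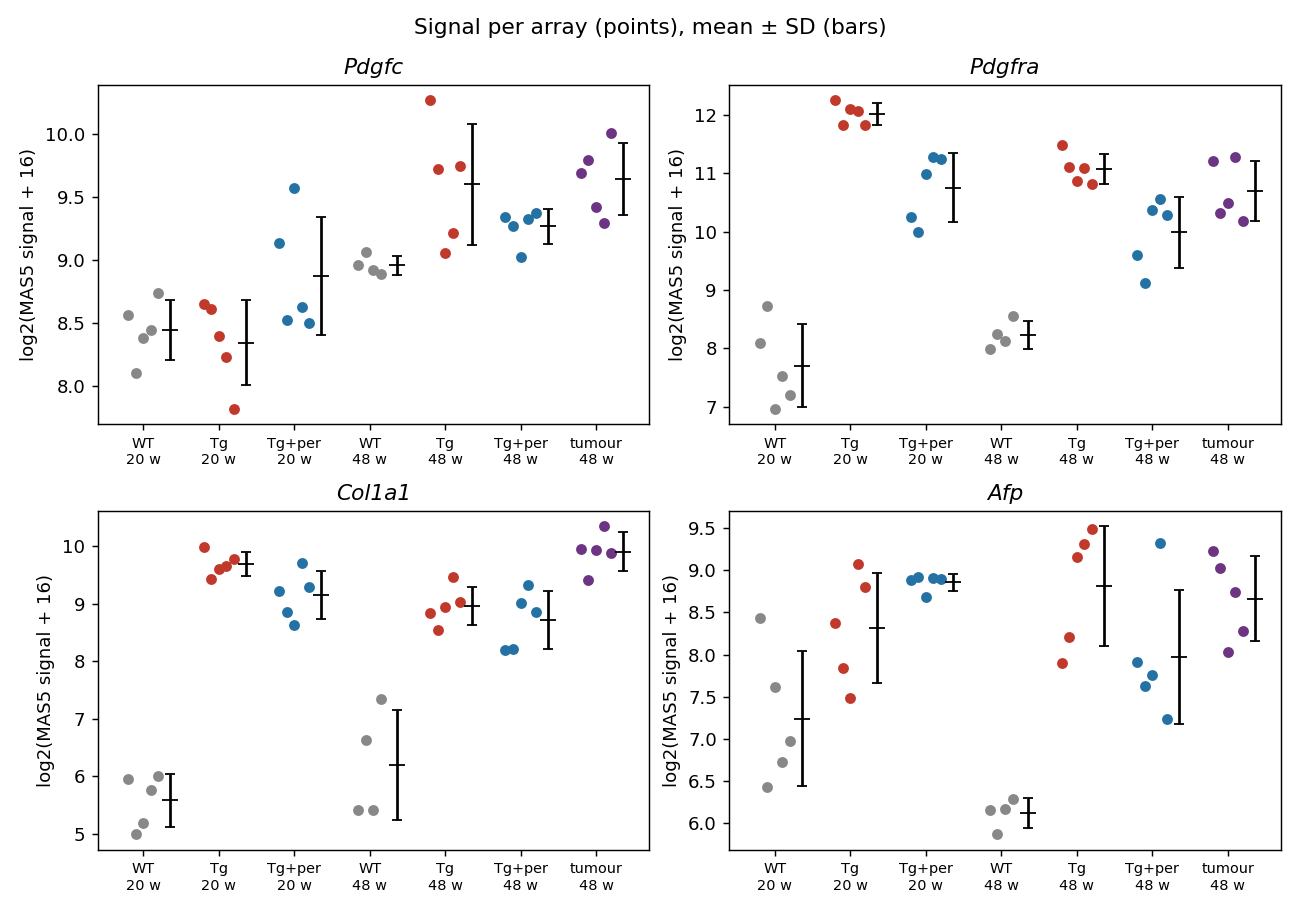
Signal of Pdgfc, Pdgfra, Col1a1 and Afp as log2(MAS5 signal + 16) on the vertical axis for each array (points) by group, with the mean and SD as bars. The 5 transgenic livers at week 20 had Pdgfra signals with a mean of 4145 against 215 in wild-type livers, and the week 48 transgenic livers had a mean Afp signal of 475 against 53.9.

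The first comparison asked what the transgene did in the liver at week 20, the stage of fibrosis. Transgenic livers held much more RNA of the receptors for PDGF and of fibrillar matrix. Pdgfra, the PDGF alpha receptor, rose 19.8-fold (log2 4.31 ± 0.29, n = 5 and 5, adjusted p = 2.07e-12), from a signal of 215 ± 122 to 4145 ± 540. Col1a1, a chain of type I collagen, rose 17.2-fold (log2 4.11 ± 0.29, adjusted p = 3.78e-12), from 33.9 ± 14.9 to 818 ± 122. Cd163 and Clec4f, which mark resident Kupffer cells, had log2 falls of -3.53 ± 0.43 and -3.16 ± 0.62. Cx3cr1, a receptor of recruited monocytes, rose by 3.27 ± 0.38. Hsd3b5, a steroid enzyme of male mouse liver, fell by 5.87 ± 1.16 (adjusted p = 0.000335). With an offset of 64 in place of 16 the log2 changes were -2.88 for Cd163, 2.59 for Cx3cr1 and -5.09 for Hsd3b5.

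Of the 21 measured genes of the extracellular matrix list, 20 rose and 1 fell, with a median log2 change of 2.31, and the counts were 20 and 1 adjusted over the list alone (camera adjusted p = 2.81e-23, and adjusted p = 0.0165 with an estimated correlation). Col6a3 rose by 3.50, Bgn (biglycan) by 3.04 and Col6a1 by 3.68, and Postn (periostin) fell by 1.35. Of 10 matrix proteases and inhibitors, 9 rose and 1 did not pass, with 9 adjusted over the list alone (median 2.05, adjusted p = 7.82e-09, and adjusted p = 0.0165 with an estimated correlation). They included Mmp2 (3.38 ± 0.30), Timp2 (2.57 ± 0.22) and Plat (2.98 ± 0.28, and 2.30 with an offset of 64). Of 6 PDGF ligands and receptors 5 rose, also adjusted over the list alone (adjusted p = 7.48e-06, and adjusted p = 0.0297 with an estimated correlation). Among them were Pdgfrb (3.39 ± 0.23) and Pdgfd (1.38 ± 0.19). Of 13 genes of TGF-beta signalling, a profibrotic pathway, 12 rose, also adjusted over the list alone (median 1.20, adjusted p = 7.82e-09, and adjusted p = 0.0165 with an estimated correlation). Ltbp1 rose by 1.61 ± 0.18 and Tgfbi by 1.97 ± 0.18. Of 13 markers of stellate cells and myofibroblasts, the matrix-forming cells of fibrotic liver, 9 rose and 4 did not pass, with 10 adjusted over the list alone (median 1.37, adjusted p = 7.82e-09, and adjusted p = 0.0297 with an estimated correlation). Vim rose by 2.14 and Cygb by 2.61. Acta2, the smooth muscle actin of activated myofibroblasts, had a change of 0.56 ± 0.32 that did not pass (limma adjusted p = 0.207). Its week 20 signals did not overlap, at 456 to 719.5 in wild-type and 774.2 to 1084.3 in transgenic liver. The error of Acta2 comes from the spread of all 7 groups, and its week 48 wild-type signals ran from 464.2 to 2597.5. Crispld2 rose from 13.5 ± 2.57, under the array medians, to 1978 ± 540. The size of such rises rests on the offset added to the signal: the log2 change of Crispld2 was 6.04 with the offset of 16, 7.07 with 1 and 4.68 with 64, and that of Col1a1 4.11, 4.67 and 3.17. Svep1, Htra1 and Mgp rose as well, by 4.34, 4.24 and 4.21 (Svep1 by 2.96 with an offset of 64).

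Immune and hepatocyte lists moved as well, with calls that rested on the preset correlation. Among recruited monocyte and macrophage markers 7 of 10 rose, also adjusted over the list alone (median 1.34, adjusted p = 6.64e-05, and adjusted p = 0.129 with an estimated correlation). Macrophage and Kupffer cell markers split: 3 of 14 rose and 3 fell, or 5 and 5 adjusted over the list alone. Timd4 fell by 2.29 (log2 -1.63 with an offset of 64), and the list was not called (adjusted p = 0.713, median 0.37 but mean -0.27). Male-biased liver genes fell in 8 of 9 cases, and in 9 adjusted over the list alone (median -1.98, adjusted p = 1.55e-07, and adjusted p = 0.0872 with an estimated correlation). They were not low in all transgenic livers: Hsd3b5 gave signals of 28.8, 12.5 and 14 in replicates 1, 2 and 3 and 6824 and 2441 in replicates 4 and 5. Acute phase genes fell in 7 of 13 cases (median -0.50, adjusted p = 5.31e-06, and adjusted p = 0.126 with an estimated correlation). Quantile normalisation ended that call. Bile acid genes fell in 7 of 13 cases, with 8 adjusted over the list alone (median -0.55, adjusted p = 8.77e-05, and adjusted p = 0.158 with an estimated correlation). Cyp7b1 had a fall of -1.98 ± 0.42 and the carrier Slco1a1 one of -2.29 ± 0.58. Mature hepatocyte functions had 5 of 16 genes lower, 7 adjusted over the list alone (median -0.23, adjusted p = 0.000424, and adjusted p = 0.32 with an estimated correlation). Quantile normalisation turned this median to 0.03 and the change of Apoa1 to 0.05 and of Cyp2e1 to 0.02. Immediate early genes (6 of 11 rose, adjusted p = 0.00246) and oncofetal and liver tumour markers (6 of 12 rose, adjusted p = 0.00848) each had adjusted p = 0.267 with an estimated correlation.

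The remaining called lists of this comparison were near the threshold. Xenobiotic metabolism (4 of 13 fell and 1 rose, adjusted p = 0.0265), fatty acid synthesis (3 of 12 fell, adjusted p = 0.0221), cholesterol synthesis (2 of 16 fell, adjusted p = 0.0356), interferon response (4 of 12 rose, adjusted p = 0.032) and T and NK cells (4 of 8 rose, adjusted p = 0.0319) had adjusted p = 0.32, 0.44, 0.657, 0.504 and 0.383 with an estimated correlation. Quantile normalisation ended the calls of the first 4 of these lists. In the filter that kept the upper 40% of probe sets the T and NK list turned to a median of -0.19. Lists that were not called included Wnt and beta-catenin targets (adjusted p = 0.137), retinoid response (0.452), cell cycle (0.452, Mcm2 alone rose, by 1.14), B and plasma cells (0.0941), endothelium (0.146), neutrophils (0.154), mesothelium (0.0941) and fatty acid oxidation (0.107). The others were erythroid cells (0.164), lipid droplet (0.918), female-biased liver genes (0.597), sex chromosome genes (0.586), bile duct cells (0.964), adipocytes (0.557), pancreatic acinar cells (0.762), skeletal muscle (0.597) and the circadian clock (0.964), where 0 of 12 genes passed. The clock and bile duct lists had medians above 0 and tests below 0.

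The groups of this comparison did not overlap in the Actb 3'/5' ratio, 1.81 to 2.16 in wild-type and 1.62 to 1.74 in transgenic liver. In all, 3102 of 13099 genes were called by limma at week 20, 2071 higher and 1031 lower. Of these, 949 changed at least 2-fold, 833 higher and 116 lower. The groups did not overlap for 2115 genes, of which 1862 were called; chance gives a share of 0.00794 with 5 against 5 arrays. The share of higher calls was 66.8% as reported, 54.7% after quantile normalisation and 46.7% after median centring (1419 higher and 1619 lower), which moved the median change of all genes from 0.06 to -0.07.

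At week 48 the same comparison asked which differences were present at the tumour stage. The PDGF receptors and matrix were again higher, and Afp, Cdk1, Mki67 and Ccnd1 were higher in transgenic than in wild-type liver too. For these genes the difference of the effect between ages was not called (limma adjusted p = 0.188, 0.263, 0.309 and 0.530). In wild-type liver Cdk1 fell from week 20 to week 48 (log2 -1.70). Mean Afp signals at week 20 were 156 in wild-type and 329 in transgenic liver. Pdgfra rose 7.21-fold (log2 2.85 ± 0.31, n = 5 and 4, adjusted p = 6.94e-08) and Col1a1 6.81-fold (2.77 ± 0.31, adjusted p = 9.79e-08), from 70.7 ± 57.0 to 495 ± 122. Afp, the alpha-fetoprotein of fetal liver and liver tumours, rose 6.45-fold (2.69 ± 0.38, adjusted p = 5.44e-06), from 53.9 ± 8.25 to 475 ± 213. Cdk1 and Mki67, which are expressed in dividing cells, rose by 2.06 ± 0.47 and 2.15 ± 0.53, and Ccnd1 (cyclin D1) rose by 1.70 ± 0.36. Cidea, a lipid droplet protein, fell by 5.59 ± 0.82, from 4132 ± 1798 to 103 ± 111. With an offset of 64 in place of 16 the log2 changes were 2.12 for Col1a1, 2.09 for Afp, 1.39 for Cdk1, 1.33 for Mki67 and -4.80 for Cidea.

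Of the 7 lists whose call held with an estimated correlation, 5 were those of week 20. Extracellular matrix had 19 of 21 genes higher and 1 lower, also adjusted over the list alone (median 1.67, adjusted p = 1.21e-15), matrix proteases 8 of 10 higher (adjusted p = 4.43e-08), PDGF genes 5 of 6 higher (adjusted p = 8.17e-06) and TGF-beta signalling 10 of 13 higher (adjusted p = 4.52e-07). Each of these 4 had adjusted p = 0.0306 with an estimated correlation. Stellate cell and myofibroblast markers rose in 8 of 13 cases (median 1.14, adjusted p = 2.03e-07, and adjusted p = 0.0418 with an estimated correlation). Among them Acta2 had a change of 0.17 (limma adjusted p = 0.765). Its signals ran from 464.2 to 2597.5 in wild-type and from 613.3 to 1670.5 in transgenic liver. Recruited monocyte and macrophage markers rose in 9 of 10 cases, also adjusted over the list alone (median 1.77, adjusted p = 2.51e-08, and adjusted p = 0.0306 with an estimated correlation). Cx3cr1 rose by 3.87 ± 0.40 and Gpnmb by 3.57 ± 0.49, and Cd163 had a fall of -4.01 ± 0.46; with an offset of 64 the values were 3.18, 2.59 and -3.09. Oncofetal and liver tumour markers rose in 6 of 12 cases and in 10 adjusted over the list alone (median 1.79, adjusted p = 1.7e-05, and adjusted p = 0.0418 with an estimated correlation). Ly6d rose by 3.56 ± 0.62 and Scd2 by 3.33 ± 0.60.

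Other lists passed with the preset correlation. Cell cycle genes rose in 8 of 22 cases and in 10 adjusted over the list alone (adjusted p = 0.00263, and adjusted p = 0.525 with an estimated correlation). Male-biased genes fell in 7 of 9 cases (median -1.38, adjusted p = 7.28e-06, and adjusted p = 0.143 with an estimated correlation). Bile acid genes fell in 7 of 13 cases (adjusted p = 0.000246, and 0.209 with an estimated correlation) and mature hepatocyte functions in 8 of 16, or 10 adjusted over the list alone (median -0.32, adjusted p = 2.31e-05, and adjusted p = 0.239 with an estimated correlation). In the last of these lists Otc fell by 0.37 and Hnf4a, a transcription factor of hepatocytes, by 0.53, whereas the fall of Apoa1 turned to 0.05 after quantile normalisation. Immune lists were higher: T and NK cells (4 of 8 rose, adjusted p = 0.0134, but a median of -0.16 with the upper 40% of probe sets), B and plasma cells (3 of 8, adjusted p = 0.0223), neutrophils (3 of 7, adjusted p = 0.0223), macrophages and Kupffer cells (5 of 14, adjusted p = 0.0204) and interferon response (3 of 12, adjusted p = 0.0249). With an estimated correlation they had adjusted p = 0.326, 0.475, 0.51, 0.559 and 0.475. Xenobiotic metabolism (5 of 13 fell and 1 rose, adjusted p = 0.0141), fatty acid oxidation (4 of 12 fell and 1 rose, adjusted p = 0.0204), acute phase (5 of 13 fell, adjusted p = 0.0223, median -0.25 but mean 0.01) and immediate early genes (4 of 11 rose, adjusted p = 0.0387) had adjusted p = 0.264, 0.475, 0.475 and 0.475 with an estimated correlation. Quantile normalisation ended the calls of the interferon, xenobiotic, fatty acid oxidation, acute phase, immediate early and mature hepatocyte lists.

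At week 48, 2720 genes were called, 1858 higher and 862 lower, and 964 changed at least 2-fold. The groups did not overlap for 2804 genes, of which 2125 were called, where chance gives a share of 0.0159 with 5 against 4 arrays. The share of higher calls was 68.3% as reported and 84.5% after median centring. Of the genes called higher, 1183 were called higher at both ages against 294 for independent lists, and of those lower 340 against 67.8. Genes called in opposite directions numbered 0 among those higher at week 20 and 2 among those lower.

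**Figure D2:**
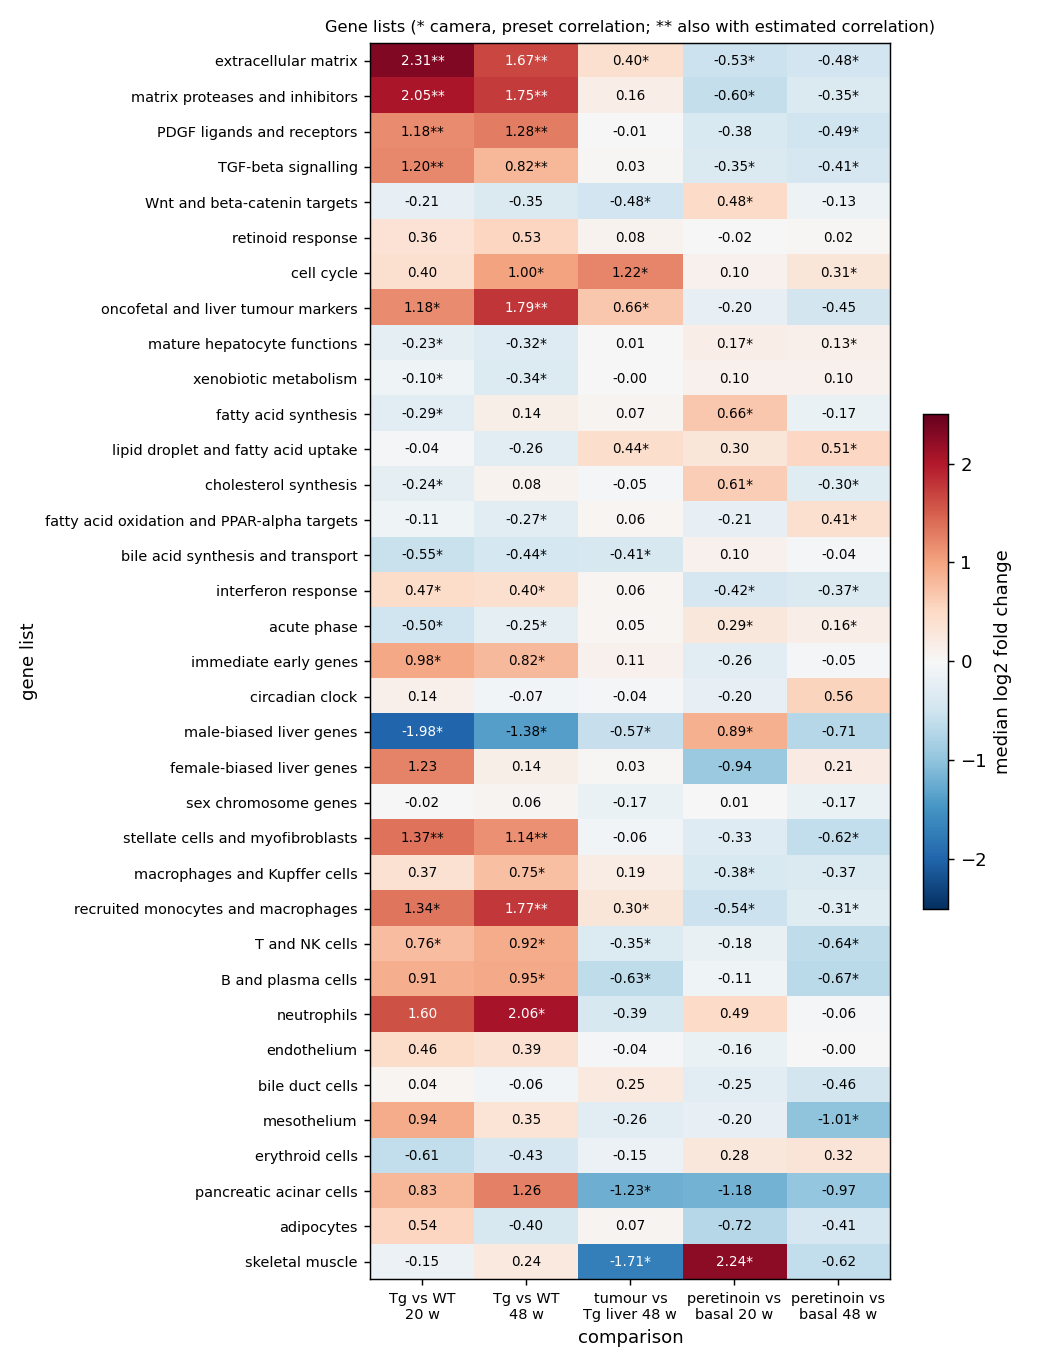
Median log2 change of each of the 35 gene lists (vertical) in the 5 main comparisons (horizontal), with 1 star for lists called by camera at the preset correlation and 2 stars for those also called with an estimated correlation. The extracellular matrix list had medians of 2.31 and 1.67 with the transgene and -0.53 and -0.48 with peretinoin; the mature hepatocyte medians at week 20 change sign after quantile normalisation.

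The transgene effect was then compared between the ages. The rise of Crispld2 was smaller at week 48 (difference of log2 changes -2.29), as was that of Tns1, a focal adhesion protein (-2.03 ± 0.35, adjusted p = 0.00794). The change of H2az2, a histone variant, was higher at week 48 by 0.81 ± 0.13 and that of Rpa3, a replication protein, by 1.03 ± 0.17 (each adjusted p = 0.00488), as were those of Zwint (0.84) and Serpina7 (2.18), and that of Eif3b was lower (-0.76). The extracellular matrix list had a smaller effect at week 48 (median -0.79, 7 of 21 genes lower adjusted over the list alone, adjusted p = 5.68e-05), and the macrophage and Kupffer cell (0.64, adjusted p = 0.000485), cell cycle (0.50, adjusted p = 0.0333) and acute phase (0.34, adjusted p = 0.0406) lists a higher one; each had adjusted p = 0.964 with an estimated correlation. In all 36 genes were called, 18 higher and 18 lower. Median centring called 60, 55 of them higher, and moved the median of all genes from -0.02 to 0.19. Leaving out 1 array gave 20, 66, 15 and 22 calls without replicates 1, 2, 3 and 5 of the week 20 wild type, and 15, 16 and 13 without replicates 2, 3 and 4 of the week 48 wild type. It gave 12 and 13 without replicates 2 and 3 of the week 20 transgenic group, and 23, 16, 22 and 16 without replicates 1, 3, 4 and 5 of the week 48 transgenic group.

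Tumours were compared with the transgenic livers of the same age to ask what set the tumour tissue apart. The labels do not say whether a tumour and a liver came from the same mouse. Genes of dividing cells had higher signals in tumours, without passing the test over all genes. Cdk1 gave 855 ± 498 in tumours and 224 ± 93.1 in livers (log2 1.75 ± 0.45, n = 5 and 5, adjusted p = 0.217), and Ly6d, an oncofetal marker, gave 6104 ± 2251 and 1586 ± 805 (1.99 ± 0.58, adjusted p = 0.257). Neither gene's groups overlapped. Glul, the glutamine synthetase of pericentral hepatocytes and a target of beta-catenin, gave 5105 ± 1520 and 11400 ± 4464 (-1.12 ± 0.33, adjusted p = 0.257), and the glutamate carrier Slc1a2 had a change of -2.12 ± 0.50 (adjusted p = 0.217). Ctnnb1, the gene of beta-catenin, had a change of 0.09 ± 0.07 (adjusted p = 0.862) and Afp one of -0.15 ± 0.36 (adjusted p = 0.978).

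As lists, these genes did move together under the preset correlation. Cell cycle genes were higher (median 1.22, 15 of 22 adjusted over the list alone, adjusted p = 2.15e-18, and adjusted p = 0.235 with an estimated correlation). Rrm2 stood at 1.20, Top2a at 1.39 and Aurka at 1.37. Wnt and beta-catenin targets were lower (median -0.48, 7 of 16 adjusted over the list alone, adjusted p = 1.75e-05, and adjusted p = 0.235 with an estimated correlation). Axin2 stood at -0.62. Bile acid genes were lower (median -0.41, 0 of 13 adjusted over the list alone) and lipid droplet genes higher (median 0.44, 2 of 11 adjusted over the list alone, Cidea at 2.48 ± 0.77), with adjusted p = 3.08e-05 and 0.000169, and both with adjusted p = 0.235 with an estimated correlation. Extracellular matrix genes were higher still than in the livers (median 0.40, 7 of 21 adjusted over the list alone, adjusted p = 3.08e-05, and adjusted p = 0.402 with an estimated correlation). Postn stood at 1.11 and Col1a1 at 0.94. Oncofetal markers (median 0.66, adjusted p = 0.00509) and recruited monocytes (0.30, adjusted p = 0.0229) were higher, and male-biased genes (-0.57, adjusted p = 0.006), B and plasma cells (-0.63, adjusted p = 0.00148) and T and NK cells (-0.35, adjusted p = 0.0281, but 0.13 with the upper 40% of probe sets) lower. With an estimated correlation these lists had adjusted p = 0.337, 0.51, 0.51, 0.402 and 0.51. Skeletal muscle (-1.71, adjusted p = 0.00509, and 0.662 with an estimated correlation) and pancreatic acinar genes (-1.23, adjusted p = 0.0444, and 0.816 with an estimated correlation) were lower in tumours than in livers of which 1, replicate 4, carried both. Without the 6 arrays with such transcripts the pancreatic median was -0.08 and the muscle call ended.

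By limma 0 of 13099 genes were called in tumours, and 1075 had an unadjusted p under 0.05; the smallest adjusted p was 0.147. Array weights gave 137 calls and the fit without the 6 arrays 4, the genes Gask1b, Mest, Tceal8 and Treh, chosen after their values were seen. With the replicate number as a block, a fit of the compared arrays did call genes. Among them were Col1a1 (log2 0.94, limma adjusted p = 0.0194) and Rrm2 (1.20, adjusted p = 0.0446). In residuals 8 of 10 arrays correlated best with the array of their own number, but the numbers were not shown to pair the samples. Leaving out replicate 5 of the transgenic livers gave 1 call and leaving out tumour replicate 4 gave 6.

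The diet comparison asked what peretinoin changed in transgenic liver at week 20. Pdgfra fell 2.39-fold with peretinoin (log2 -1.26 ± 0.29, n = 5 and 5, adjusted p = 0.0179), from 4145 ± 540 to 1823 ± 681, against 215 ± 122 in wild-type liver. Pdgfb, a PDGF ligand, fell by 0.94 ± 0.22 (adjusted p = 0.0213) and Timp3, an inhibitor of matrix proteases, by 1.36 ± 0.27 (adjusted p = 0.00773). Insig1, a regulator of sterol synthesis, rose 2.19-fold (1.13 ± 0.14, adjusted p = 6.57e-05), from 1423 ± 232 to 3153 ± 615, and Scd1, a desaturase of fatty acid synthesis, rose by 0.67 ± 0.13 (adjusted p = 0.00701). Serpina7, the thyroxine-binding globulin, rose 4.17-fold (2.06 ± 0.31, adjusted p = 0.00093). These arrays also differed in RNA quality: the Actb 3'/5' ratio was 2.52 ± 0.578 (n = 5) with peretinoin and 1.69 ± 0.0558 (n = 5) on the basal diet, and with it as a covariate 0 genes were called by limma (949 at an unadjusted p under 0.05).

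Fatty acid synthesis genes were higher with peretinoin (median 0.66, 1 of 12 rose, 9 adjusted over the list alone, adjusted p = 9.82e-07), as were those of cholesterol synthesis (median 0.61, 2 of 16 rose, 4 adjusted over the list alone, adjusted p = 4.22e-06). Both lost the call with an estimated correlation (adjusted p = 0.351). Higher too were Wnt and beta-catenin targets (median 0.48, 2 of 16 adjusted over the list alone, adjusted p = 0.000243), acute phase genes (0.29, 6 of 13 adjusted over the list alone, adjusted p = 0.000243) and male-biased genes (0.89, 1 of 9 rose, 5 adjusted over the list alone, adjusted p = 0.000132), each again with 0.351 with an estimated correlation. Extracellular matrix genes were lower (median -0.53, 1 of 21 fell, 2 adjusted over the list alone, adjusted p = 6.08e-05, and 0.351 with an estimated correlation), with Col4a2 at -0.72 and Col1a1 at -0.55 (adjusted p = 0.299). Matrix proteases (-0.60, 2 of 10 fell, adjusted p = 0.00136), TGF-beta signalling (-0.35, adjusted p = 0.0042), interferon response (-0.42, 5 of 12 adjusted over the list alone, adjusted p = 0.000679) and recruited monocytes (-0.54, 4 of 10 adjusted over the list alone, adjusted p = 0.0042) were lower as well, likewise with adjusted p = 0.351 with an estimated correlation. Mature hepatocyte functions (0.17, adjusted p = 0.00989, but -0.06 after quantile normalisation), macrophages and Kupffer cells (-0.38, adjusted p = 0.0126) and skeletal muscle (2.24, adjusted p = 0.0161) had adjusted p = 0.546 with an estimated correlation. The muscle list was carried by replicates 3 and 5 of the peretinoin group, and its median was -0.09 without the 6 arrays with other tissue transcripts. Quantile normalisation ended the acute phase call. The male-biased list had mean log2 signals of 9.12 to 9.66 in transgenic replicates 1 to 3 and of 11.96 and 11.47 in replicates 4 and 5. With peretinoin they ran from 10.35 in replicate 5 to 13.06 in replicate 3, so the groups overlapped.

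The retinoid response list was not called (adjusted p = 0.657, median -0.02 but a test above 0). Tgm2, a transglutaminase induced by retinoids, rose by 0.75 ± 0.19 (adjusted p = 0.026). Cyp26a1, the retinoid-degrading enzyme, had a change of -0.12 ± 0.31 (adjusted p = 0.881) and Rarb, a retinoic acid receptor, one of -0.38 ± 0.23 (adjusted p = 0.37). PDGF genes (adjusted p = 0.0755, 2 of 6 fell) and stellate cell markers (adjusted p = 0.0818, 1 of 13 fell) were not called either. The largest rises were those of Hectd2os (2.41), Serpina7, Fitm1 (1.31), Derl1 (1.22) and Rab26os (1.15), and the largest falls those of Lrtm2 (-2.15), Cyp39a1 (-1.76), Thsd7a (-1.72), Spon1 (-1.61) and Htra3 (-1.57).

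The signature of the transgene, taken from week 48, gave a score of -2.21 ± 0.292 (SD, n = 5) in wild-type liver at week 20, -0.49 ± 0.139 (n = 5) in transgenic liver and -0.92 ± 0.286 (n = 5) with peretinoin. Over its 1405 genes that rose and 404 that fell, the mean score with peretinoin differed by -0.427 from that on the basal diet, 24.9% of the gap to wild type (exact permutation test, two-sided p = 0.0317). Scores within the peretinoin group were set beside RNA quality, and their relation was not tested. Replicate 5, with an Actb ratio of 1.70, scored -0.45, within the basal diet range of -0.64 to -0.30. Replicates 1 to 4, with ratios of 2.38 to 3.31, scored -1.14 to -0.85. Among these the lowest ratio (replicate 4) went with -0.85 and the highest (replicate 2) with -1.08, while replicate 3 (2.54) scored -1.14. Replicate 5 was also the highest of its group in muscle transcripts and correlated least with it. Without replicate 1 or 3 of the transgenic group the difference was -0.378 or -0.416 (exact p = 0.0556 for each).

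**Figure D3:**
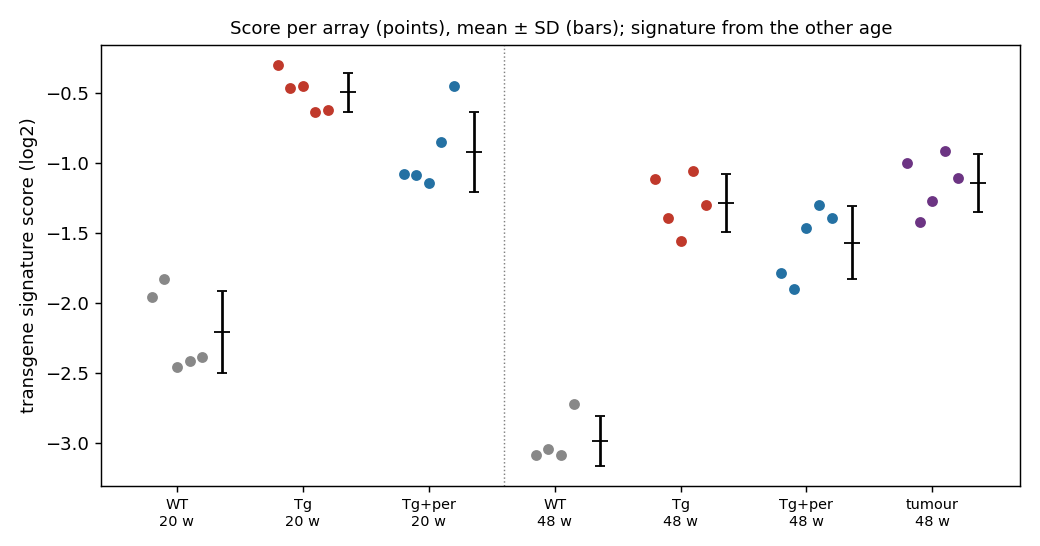
Transgene signature score (log2, from the genes called at the other age) on the vertical axis for each array (points) by group, with the mean and SD as bars and a dotted line between the ages, whose scores use different genes. At week 20 the mean with peretinoin was -0.92, against -0.49 in transgenic and -2.21 in wild-type liver, and replicate 5 with peretinoin lay at -0.45.

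In all, 378 genes were called with peretinoin at week 20, 215 higher and 163 lower, and 68 changed at least 2-fold, 45 of them lower. The groups did not overlap for 657 genes, of which 195 were called, where chance gives a share of 0.00794. Median centring called 163, 73 higher and 90 lower, and a fit of the compared arrays alone 229. A fit without the 6 arrays called 658, array weights 1516 and the clock components as covariates 9. A fit of the compared arrays with the replicate number as a block ended every call, though the numbers were not shown to pair the samples. Leaving out 1 array gave 142, 104 and 81 calls without transgenic replicates 1, 2 and 3, 104, 51 and 139 without peretinoin replicates 1, 2 and 3, and 879 without peretinoin replicate 5.

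**Figure D4:**
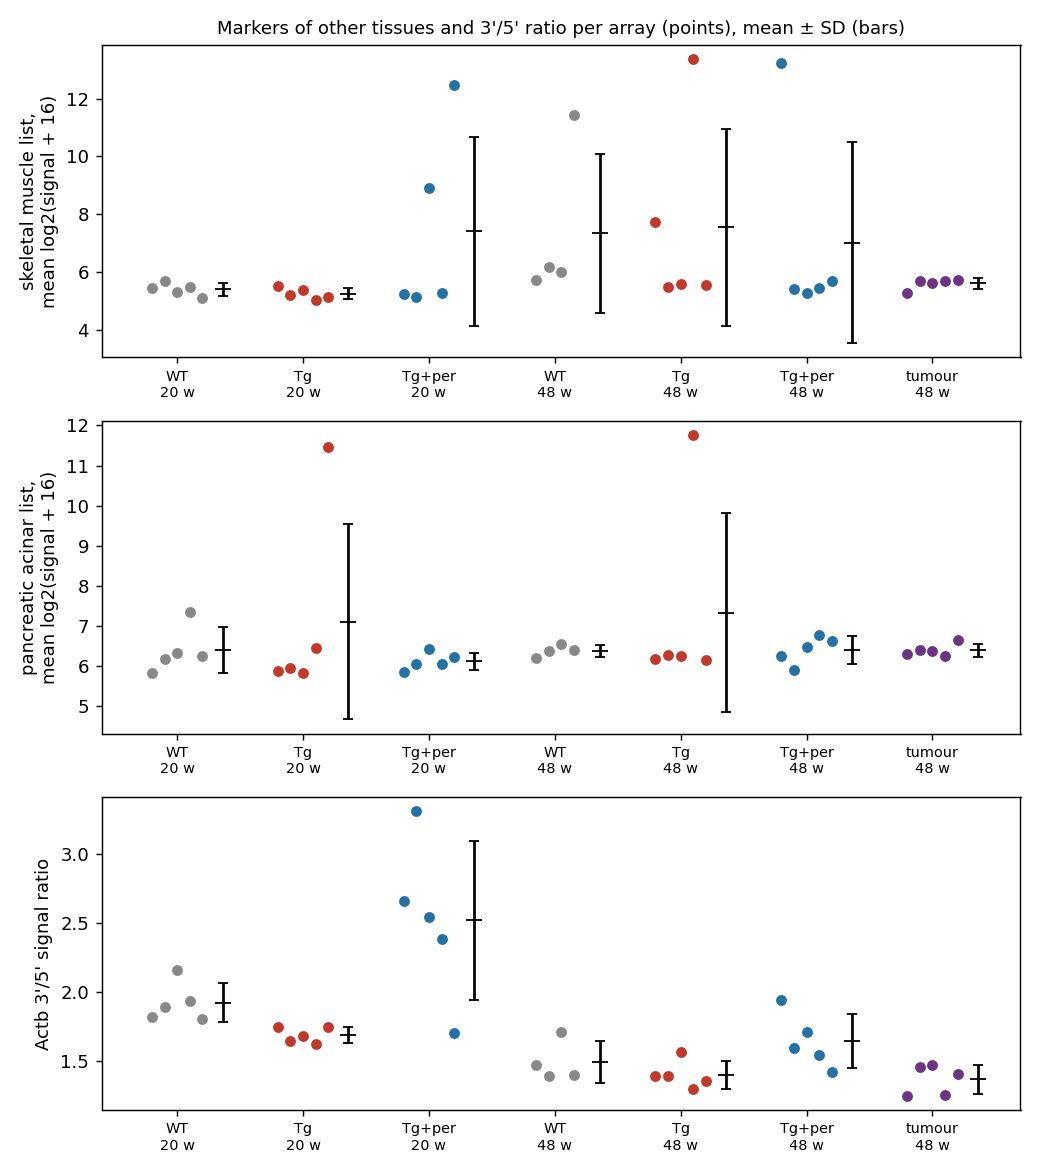
Mean log2(signal + 16) of the skeletal muscle list (top) and of the pancreatic acinar list (middle), and the ratio of Actb 3' to 5' signal (bottom), for each array (points) by group, with the mean and SD as bars. The Actb ratio had a mean of 2.52 in the week 20 peretinoin group and 1.69 in the transgenic group, and single arrays in several groups stood far above the others in muscle or pancreas transcripts.

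At week 48 the diet comparison asked the same of livers at the tumour stage. Dpt (dermatopontin) fell 6.11-fold (log2 -2.61 ± 0.45, n = 5 and 5, adjusted p = 0.0028), from 1702 ± 593 to 304 ± 201, and Abi3bp fell 3.79-fold (-1.92 ± 0.25, adjusted p = 0.000149). Pdgfd, a PDGF ligand, fell 2.14-fold (-1.10 ± 0.19, adjusted p = 0.0028), from 302 ± 57.9 to 134 ± 35.4, against 96.5 ± 25.4 (n = 4) in wild-type liver. Thbs2 (-1.34 ± 0.25), Timp2 (-1.07 ± 0.22) and the fibroblast cadherin Cdh11 (-2.01 ± 0.40, and -1.30 with an offset of 64) fell as well. Pdgfra had a change of -1.09 ± 0.29 that did not pass (adjusted p = 0.0678). The Actb 3'/5' ratio was 1.64 ± 0.195 (n = 5) with peretinoin and 1.40 ± 0.101 (n = 5) on the basal diet. With it as a covariate 27 of 13099 genes were called in place of 95. The poly-A control Dap gave 7910 ± 5804 (n = 5) with peretinoin and 3213 ± 1093 (n = 5) on the basal diet.

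Stellate cell and myofibroblast markers were lower (median -0.62, Cygb alone fell, 7 of 13 adjusted over the list alone, adjusted p = 6.74e-05), as were PDGF genes (-0.49, 1 of 6 fell, 3 adjusted over the list alone, adjusted p = 0.000583). Both lost the call with an estimated correlation (adjusted p = 0.261). Lower too were TGF-beta signalling (-0.41, 3 of 13 adjusted over the list alone, adjusted p = 0.00133), T and NK cells (-0.64, Cd3g fell, adjusted p = 0.00232) and mesothelium (-1.01, 3 of 4 adjusted over the list alone, adjusted p = 0.00431), each again with 0.261 with an estimated correlation. Genes of fatty acid oxidation were higher (0.41, 2 of 12 adjusted over the list alone, adjusted p = 6.74e-05), with Angptl4 at 1.33 ± 0.44, likewise with adjusted p = 0.261 with an estimated correlation. Extracellular matrix (-0.48, adjusted p = 0.00424), B and plasma cells (-0.67, adjusted p = 0.000882), interferon response (-0.37, adjusted p = 0.00431), recruited monocytes (-0.31, adjusted p = 0.0121), matrix proteases (-0.35, adjusted p = 0.0244) and cholesterol synthesis (-0.30, adjusted p = 0.0194) were lower, with adjusted p = 0.451, 0.341, 0.376, 0.376, 0.376 and 0.633 with an estimated correlation. Mature hepatocyte functions (0.13, adjusted p = 0.000882), lipid droplet (0.51, adjusted p = 0.00652), acute phase (0.16, adjusted p = 0.0345) and cell cycle (0.31, adjusted p = 0.0483) were higher, with adjusted p = 0.376, 0.376, 0.46 and 0.676 with an estimated correlation. Quantile normalisation ended the hepatocyte and acute phase calls. The fit without the 6 arrays ended those of matrix, matrix proteases, recruited monocytes, cholesterol synthesis and acute phase.

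The retinoid response list was not called (adjusted p = 0.595), with Rarb at -0.69 (adjusted p = 0.151) and Cyp26a1 at -0.66 (adjusted p = 0.348), and Afp had a change of -0.84 (adjusted p = 0.283). The clock list had a median of 0.56 (adjusted p = 0.0825), and the clock gene Dbp gave 3432, 6853 and 4109 in peretinoin replicates 1 to 3 and 360.5 and 608.6 in replicates 4 and 5. The signature taken from week 20 gave -1.28 ± 0.206 (n = 5) in transgenic liver, -1.57 ± 0.260 (n = 5) with peretinoin, -2.98 ± 0.177 (n = 4) in wild-type liver and -1.14 ± 0.205 (n = 5) in tumours. The difference between diets was -0.284, 16.7% of the gap (exact permutation test, two-sided p = 0.111), and -0.351 after median centring (exact p = 0.0476).

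In all, 95 genes were called at week 48, 20 higher and 75 lower, and 44 of the 45 that changed at least 2-fold were lower. In 353 genes the groups did not overlap, and 76 of these were called, where chance gives a share of 0.00794. Quantile normalisation and median centring each called 55 genes, with 27.3% and 38.2% higher against 21.1% as reported. A fit of the compared arrays alone called 4, no filter 62, the fit without the 6 arrays 40, the Actb covariate 27 and the clock covariates 38. Adding the replicate number as a block to the fit of the compared arrays ended every call, though the numbers were not shown to pair the samples. Leaving out 1 array gave 63, 36 and 46 calls without transgenic replicates 1, 2 and 5, and 57, 26, 146 and 180 without peretinoin replicates 1 to 4. Of the genes lower with peretinoin 7 were called at both ages against 0.933 for independent lists, and of those higher 1 against 0.328. The lists are not independent, since both ages shared 1 estimate of each gene's spread. The Actb 3'/5' ratio was also higher with peretinoin at both ages, 2.52 against 1.69 at week 20 and 1.64 against 1.40 at week 48. Genes called in opposite directions numbered 1 among those higher at week 20 and 0 among those lower.

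The peretinoin effect was then compared between the ages. This difference and that of the transgene effect use the same transgenic livers of the basal diet, with opposite signs. Genes called in both, such as Serpina7 and Rpa3, are therefore not separate results. Insig1 rose at week 20, and its effect was lower at week 48 by 1.07 ± 0.20 (log2 -1.07, adjusted p = 0.0135), as were those of Sc5d (-0.92, adjusted p = 0.0455), Serpina7 (-2.60 ± 0.43, adjusted p = 0.006), Hectd2os (-3.45 ± 0.65) and Derl1 (-1.18). The effect on Abi3bp (-1.65) was lower at week 48 too, as were those on Dcps (-0.83 ± 0.14) and Rpa3 (-0.88), and that on Ripk4 was higher (1.12 ± 0.20). Cholesterol synthesis (2 of 16 called, 9 adjusted over the list alone, adjusted p = 4.55e-08), fatty acid synthesis (-0.99, 7 of 12 adjusted over the list alone, adjusted p = 1.22e-05), male-biased genes (-1.10, 5 of 9 adjusted over the list alone, adjusted p = 1.22e-05) and Wnt targets (-0.47, adjusted p = 0.00131) had a lower effect at week 48, and fatty acid oxidation a higher one (0.72, 4 of 12 adjusted over the list alone, adjusted p = 0.000865). With an estimated correlation these 5 lists had adjusted p = 0.391, 0.367, 0.367, 0.391 and 0.391. In all 89 genes were called, 40 higher and 49 lower; median centring called 48, of which 77.1% were higher. The count was 10 with the Actb ratio and 8 with the clock components as covariates, and 407 with array weights. Leaving out 1 array gave 24, 21, 11, 215 and 173 calls without replicates 1 to 5 of the week 20 transgenic group, and 45, 22, 57 and 30 without replicates 2 to 5 of the week 48 transgenic group. It gave 23, 18, 21 and 204 without replicates 1, 2, 3 and 5 of the week 20 peretinoin group, and 43, 167 and 32 without replicates 2, 4 and 5 of the week 48 peretinoin group.

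The ages were also compared within each genotype. Age and any hybridisation batch cannot be told apart from the labels. The mean signal of the poly-A control Dap was 5872 and 5995 in wild-type and transgenic liver at week 20. At week 48 it was 3192 and 3213. In wild-type liver Cidea rose 53.2-fold from week 20 to week 48 (log2 5.73 ± 0.82, n = 4 and 5, adjusted p = 9.22e-05), from 72.7 ± 59.8 to 4132 ± 1798 (log2 4.94 with an offset of 64), and the related lipid droplet gene Cidec rose by 2.44 ± 0.72. The clock output gene Dbp fell by 3.79 ± 0.77 (adjusted p = 0.0034), from 5910 ± 3194 to 487 ± 434, and Per3 fell by 2.32 (log2 -1.56 with an offset of 64). Arntl, a positive regulator of the clock, rose by 1.72 ± 0.42 (adjusted p = 0.0117). Of 12 clock genes 3 rose and 4 fell, 3 and 5 adjusted over the list alone, and a test in 1 direction did not call the list (adjusted p = 0.608). Lipid droplet (2 of 11 rose, adjusted p = 0.0224) and cholesterol synthesis genes (Hmgcs1 alone rose, adjusted p = 0.016) were called, both with adjusted p = 0.992 with an estimated correlation. Of 901 genes called, 316 were higher and 585 lower, and 17.7% were higher after median centring against 35.1%. The groups did not overlap for 1158 genes, 631 of them called, where chance gives a share of 0.0159. The ages did not overlap in the Actb 3'/5' ratio, 1.81 to 2.16 at week 20 and 1.39 to 1.71 at week 48. A fit of the compared arrays alone called 302 genes, the clock covariates 271, the Actb covariate 537 and the fit without the 6 arrays 557. Leaving out replicate 2 of the week 20 group gave 581 calls, and leaving out replicates 2, 3 and 4 of the week 48 group gave 556, 528 and 518.

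In transgenic liver Dbp fell by 3.17 ± 0.73 (n = 5 and 5, adjusted p = 0.00347), from 5208 ± 1465 to 868 ± 724, and Per3, Ciart and Usp2 had falls of -2.57 ± 0.39, -3.06 and -2.63. Npas2 rose by 2.66 ± 0.45. With an offset of 64 Per3, Ciart and Npas2 had log2 changes of -1.95, -1.99 and 1.62. Of 12 clock genes 3 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.142). Elovl3, a fatty acid elongase, rose by 4.18 ± 0.78, and Lcn2 and Orm2, both acute phase proteins, by 2.79 and 2.45. Pdgfra and Col1a2 fell by 0.94 and 1.10. Cholesterol synthesis (5 of 16 rose, 10 adjusted over the list alone, median 0.81, adjusted p = 3.49e-06), fatty acid synthesis (5 of 12 rose and 1 fell, adjusted p = 0.00303), macrophages and Kupffer cells (4 of 14 rose, adjusted p = 0.000613) and recruited monocytes (1 of 10 rose, adjusted p = 0.0273) were higher, each with adjusted p = 0.782 with an estimated correlation. Lower, again with 0.782, were extracellular matrix genes (6 of 21 fell, 8 adjusted over the list alone, median -0.60, adjusted p = 0.00303). Acute phase (adjusted p = 0.05) and skeletal muscle (median 2.23, adjusted p = 0.05), both under the threshold before rounding, had adjusted p = 0.855 and 0.899 with an estimated correlation. Replicate 4 of the week 48 group carried the muscle transcripts (list mean 13.37). Replicate 1 of that group was raised too (7.74), by less than the margin of 3 log2 units. Of 2063 genes called, 785 were higher (38.1%) and 1278 lower, and 68.7% were higher after median centring. The Actb 3'/5' ratio was 1.62 to 1.74 at week 20 and 1.30 to 1.57 at week 48; with it as a covariate 1803 genes were called, and with the clock components 85. The groups did not overlap for 1873 genes, 1375 of them called, where chance gives a share of 0.00794.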

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

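Of the tests below, those of an effect of genotype, diet or age on the muscle transcripts, and those of age and of time of day for the clock genes, were chosen only after the result was seen, as were the fits without the 6 arrays with other tissue transcripts and with the Actb ratio or the clock components as covariates. The spread given for shares of the peretinoin changes was added after the shares were seen, and so was the upper limit of the correlation given for the clock genes.

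Of 154 groups of 4 or 5 values tested, 16 had a sample far from the others, where chance gives about 1 in 20 groups. In array quality these were the Gapdh 3'/5' ratio of replicate 3 of the week 20 wild type (0.848) and the correlation with the rest of the group in replicate 5 of the week 20 peretinoin group (0.964) and replicate 4 of the week 48 transgenic group (0.945). For skeletal muscle genes they were the mean log2 signals of replicate 4 of the week 48 wild type (11.43), replicate 4 of the week 48 transgenic group (13.37), replicate 1 of the week 48 peretinoin group (13.22) and tumour replicate 1 (5.29). For pancreatic acinar genes they were replicate 5 of the week 20 transgenic group (11.45) and replicate 4 of the week 48 transgenic group (11.76). Among the panel genes they were the log2 signals of Pdgfc in replicate 3 (9.03) and Glul in replicate 4 (11.25) of the week 48 peretinoin group, Timp1 in replicate 1 of the week 48 transgenic group (7.15) and Ctnnb1 in replicate 3 of the week 48 wild type (13.37). At week 20 they were Afp in replicate 3 of the peretinoin group (8.68) and Cyp26a1 in replicate 3 of the transgenic group (12.10). The signature score of replicate 4 of the week 48 wild type (-2.72) was the last.

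The differences between ages of the transgene and peretinoin effects use the same transgenic livers of the basal diet, with opposite signs. Serpina7 and Rpa3, named in both with opposite signs, are therefore not separate results. Both effects were compared between the ages by a test of the difference. The transgene effect passed it for 36 genes, although chance was not excluded for this count (below), among them H2az2 (0.81), Rpa3 (1.03), Tns1 (-2.03), Zwint (0.84), Eif3b (-0.76), Crispld2 (-2.29) and Serpina7 (2.18), and for the extracellular matrix (-0.79), cell cycle (0.50), acute phase (0.34) and macrophage and Kupffer cell (0.64) lists. Each of these lists lost its call with an estimated correlation (adjusted p = 0.964). The peretinoin effect passed it for 89 genes, among them Serpina7 (-2.60), Dcps (-0.83), Ripk4 (1.12), Rpa3 (-0.88), Hectd2os (-3.45), Derl1 (-1.18) and Abi3bp (-1.65). It also passed for the Wnt (-0.47), fatty acid synthesis (-0.99), cholesterol synthesis (-1.001), fatty acid oxidation (0.72) and male-biased (-1.10) lists, which all lost their calls with an estimated correlation (adjusted p = 0.367 to 0.391). A signal was also present in probe sets without exactly 1 gene symbol, which the comparisons left out. Of the 3755 such probe sets with a mean signal in the upper 60% of all probe sets, 251 were higher and 131 lower with the transgene at week 20, and 224 higher and 321 lower at week 48.

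The arrays of each comparison were also split in other ways, 100 splits each with the real one included. Chance was counted as excluded where fewer than 5 splits gave as many calls. It was excluded for the transgene at week 20 (1 split with as many, 3102 calls against 1692 at most in the others) and at week 48 (1, 2720 against 1723), and for age in wild-type (1, 901 against 356) and transgenic mice (1, 2063 against 218). By this rule alone it was excluded for peretinoin at week 20 (1, 378 against 374), at week 48 (1, 95 against 62) and for its difference between ages (1, 89 against 25). The split with 374 calls exchanged replicate 5 of the week 20 transgenic group with replicate 5 of the peretinoin group. At week 20 the count thus hardly sets the real grouping apart from a mixed one. Leaving out 1 array gave 51 to 879 calls at week 20 and 26 to 180 at week 48. At each age 100 of 126 distinct splits were used. For tumours the real count was 0 by limma (1075 genes at an unadjusted p under 0.05, 10 calls at most in the other splits), so all 100 splits had as many and the splits say nothing about chance. Chance was not excluded for the difference of the transgene effect between ages (5 splits with as many as 36, 1174 at most). The split with 1174 exchanged labels at week 20, which turns the transgene effect itself into a difference between ages, a structure of the samples. The other splits of this comparison exchanged genotype labels within an age in the same way. These splits therefore cannot decide whether the 36 calls are chance.

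Muscle transcripts were high in 5 liver arrays: replicate 4 of the week 48 wild type, replicate 4 of the week 48 transgenic group, replicates 3 and 5 of the week 20 peretinoin group and replicate 1 of the week 48 peretinoin group. An effect of genotype, diet or age was argued against, since at most 2 arrays of any group were high. A mislabelled array of muscle was argued against too, since the mature hepatocyte list changed by -0.213 at the lowest and 0.03 at the highest against the rest of the group. Skeletal muscle in the sample is a candidate source: 15 muscle genes outside the marker list had a median excess of 5.04 log2 units, from 1.77 to 6.24 between arrays, and 0 of the 8 listed genes are in another list. The muscle creatine kinase Ckm gave signals of 5121 in the wild-type array, 18065 in the transgenic one, 672 and 8709 in the week 20 peretinoin arrays and 14031 in the week 48 peretinoin array. No sort or gate is named in the labels, and how such tissue came into the samples was not tested.

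The peretinoin calls at week 20 stood beside a shift of RNA quality, so each peretinoin array was compared with transgenic replicates 4 and 5 in genes called without these 3 arrays. The median signed change was 0.0071 in replicate 5, whose Actb 3'/5' ratio of 1.70 was the lowest of the group. It was 0.286, 0.338, 0.348 and 0.213 in replicates 1 to 4. Replicate 5 was also the highest of its group in muscle transcripts (12.49) and correlated least with it (0.964). Of the reference arrays, transgenic replicate 5 carried pancreas transcripts. Hsd3b5 in both (6824 and 2441) lay far above transgenic replicates 1 to 3 (12.5 to 28.8). RNA quality may explain much of these calls, but this comparison rests on 1 array that differs in several ways. With the Actb ratio as a covariate the median absolute change went from 0.60 (median standard error 0.145) to 0.37 (0.194), 62.7% of its size, and 0 of 378 genes stayed called (by limma, with 949 of all genes at an unadjusted p under 0.05), since the changes shrank and their errors grew. Time of day as the whole cause was argued against by 86.8% of the median change (SE 4.60) that was left with clock components in the fit, although 9 genes stayed called (0.52, error 0.156); the share was judged by its value alone, then with a margin of 2 SE and then of 1 SE, both added after it was seen, and with 2 SE this explanation would stay open. Without the 6 arrays 304 of 378 genes stayed called, which argues against muscle tissue for those 304 genes. The median change was then 114% (SE 15.1) of its size. That share says little about muscle, since the arrays left out include replicate 5, which showed almost no change (0.0071). An effect of the diet stays open.

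Clock genes differed between the ages in both genotypes, with Dbp lower at week 48. For RNA quality 1 relation was computed, between Dbp and the Actb 3'/5' ratio within the groups of week 20 (15 arrays). Pearson r was -0.272 (permutation p = 0.333) and Spearman rho -0.2 (permutation p = 0.470). The upper 95% limit of r was 0.279, and r was -0.03 without the 2 farthest arrays. Dbp thus did not follow the ratio over these arrays, which cannot decide for the shift between ages. That shift was seen on the basal diet, where the ratio varied little within groups (1.62 to 1.74 in transgenic and 1.81 to 2.16 in wild-type liver). It varied more with peretinoin (1.70 to 3.31), and week 48 arrays were not used. RNA quality therefore stays open. Age alone and time of day at sampling cannot be told apart here, since the sampling times are not given. At week 48 there were 3 arrays that reached the lowest Dbp signal of week 20 (2298), but all were of the peretinoin diet, with which Dbp had a change of 1.73 at week 48 that did not pass (adjusted p = 0.273); 0 livers of the basal diet did (1715 at most). That 16 of 16 pairs of gene and genotype moved as opposite phases would decides nothing, because the 8 genes were chosen after their shifts were seen, and the 4 others were mixed. Nr1d2 fell in both genotypes (-1.17 in each, adjusted p = 0.018 in wild-type and 0.00538 in transgenic mice). Per1 fell in transgenic mice (-1.55, adjusted p = 0.0244) but was not called in wild-type mice (-0.85). Nr1d1 (0.27 in wild-type and -0.18 in transgenic mice) and Cry1 (0.44 and 0.27) were not called.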

How the results depend on the processing

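The fit without the 6 arrays with muscle or pancreas transcripts, the Actb ratio as a covariate and the 2 clock components as covariates were chosen after seeing the data; the other alternatives were fixed before the data were examined. For named genes called as reported, 6856 of 7775 values under an alternative kept direction and call, 912 lost the call and 7 reversed. For called lists 710 of 863 values kept both, 146 lost the call and 7 reversed. Among genes and lists not called as reported, 547 and 47 values gained a call. The arrays carry no counts, so their number limits the precision. Where a sentence does not give it, the cause was not tested.

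With a 1.5-fold minimum, which drops small changes by construction, the count was 1822 for the transgene at week 20, 195 for peretinoin at week 20, and 476 and 996 for age in wild-type and transgenic mice. With each probe set on its own, which tests more features, it was 4102 for the transgene at week 48, 1065 and 173 for peretinoin at week 20 and 48, and 1501 and 3549 for the ages. Median centring gave 163 and 55 for peretinoin at the 2 ages, 60 for the difference of the transgene effect and 48 for that of the peretinoin effect, and quantile normalisation 55 for peretinoin at week 48. Without a filter the counts were 62 for peretinoin at week 48 and 20 and 48 for the 2 differences. With the upper 40% of probe sets the count was 136 for the peretinoin difference. Averaged probe sets gave 57 and 54 for the differences. Array weights gave 137 for tumours, 1516 for peretinoin at week 20, 3377 for age in transgenic mice, and 109 and 407 for the differences. The compared arrays alone, which leaves fewer arrays for the spread, gave 229 and 4 for peretinoin, 302 for age in wild-type mice and 27 for the peretinoin difference.

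Without the 6 arrays the counts were 4 for tumours, 658 and 40 for peretinoin at week 20 and 48, 557 for age in wild-type mice, and 15 and 135 for the differences. With the Actb ratio they were 0 for peretinoin at week 20 (by limma, with 949 genes at an unadjusted p under 0.05), 27 for peretinoin at week 48, 537 for age in wild-type mice and 10 for the peretinoin difference. With the clock components they were 9 and 38 for peretinoin, 271 and 85 for the ages, and 22 and 8 for the differences.

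The replicate numbers were not shown to pair the samples: between same-number arrays of a comparison residuals correlated from -0.0802 to 0.432, and in 0 comparisons was every pair over 0.1 or did every array correlate best with its own number. Tumours and livers at week 48 came nearest by these counts, at most a hint from the data and not the design. There 4 of 5 pairs were over 0.1 (lowest 0.0771, mean 0.186 against -0.0464 for other pairs), and 8 of 10 arrays correlated best with their own number. The mean was not particular to them. Transgenic and wild-type livers at week 48, which cannot share a mouse, also had 0.186 (against -0.0585, 3 of 4 pairs over 0.1). Peretinoin and basal diet livers at week 48 had 0.127 (against -0.0206). With the number as a block the counts were 16 for tumours, 0 and 0 for peretinoin at week 20 and 48 (by limma, with 2718 and 1720 genes at an unadjusted p under 0.05), 155 for age in wild-type mice and 19 for the peretinoin difference. The block was fitted to the compared arrays alone, so fewer arrays gave the spread and the block was not the only change.

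Leaving out each array in turn gave 2512 to 3412 calls for the transgene at week 20, 2075 to 2631 at week 48, 0 to 6 for tumours, 51 to 879 and 26 to 180 for peretinoin, 518 to 854 and 1501 to 2035 for the ages, and 12 to 66 and 11 to 215 for the differences. The signature difference of -0.427 at week 20 ranged from -0.545 to -0.372 with 1 array left out, and lost its call without replicate 1 (-0.378) or replicate 3 (-0.416) of the transgenic group, and under the replicate block (exact p = 0.125, where 0.0625 is the smallest possible). That at week 48 gained a call under median centring (-0.351, exact p = 0.0476).

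Quantile normalisation reversed Cyp2e1 (0.0196) and Apoa1 (0.0483) with the transgene at week 20, Apoa1 (0.0506) at week 48, and the mature hepatocyte list with the transgene (0.0310) and peretinoin (-0.0555) at week 20. Averaged probe sets reversed Uty with the transgene at week 48 (-0.12). The clock components reversed Arntl (-0.15) and Tef (0.10) with age in wild-type mice and Ciart (0.71) in transgenic mice, which removes the clock by construction. With the upper 40% of probe sets the T and NK cell list reversed with the transgene at week 20 (-0.19) and week 48 (-0.16) and in tumours (0.13). In that filter fewer of its genes were tested. Without the 6 arrays the skeletal muscle list reversed with peretinoin at week 20 (-0.0906), and the pancreatic acinar list in tumours turned in the test's direction alone, with a median of -0.0752 that stayed below 0, since arrays that carried these transcripts were left out.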

Other observations

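The comparison of tumours with wild-type liver at week 48 and the look at male-biased genes in single livers were chosen after the data had been seen. Tumours differed from wild-type liver of the same age in 3548 genes by limma, 2341 higher and 1207 lower, and in 3386 without the 6 arrays with other tissue transcripts. Cdk1 and Mki67, which mark dividing cells, rose from mean signals of 45.3 and 29.9 to 855 and 538 (n = 4 and 5, adjusted p = 4.1e-07 and 7.59e-06). The wild-type means lay under the array medians of that group (74.6 to 92.3), so the size of these rises rests on the offset. In all 19 of 22 cell cycle genes rose (camera adjusted p = 5.11e-10, and adjusted p = 0.193 with an estimated correlation). Oncofetal and liver tumour markers rose in 11 of 12 cases (adjusted p = 4.32e-07, and adjusted p = 0.0235 with an estimated correlation), with Ly6d at 5.54 ± 0.62 and Afp, also under those medians in wild-type liver (53.9), at 2.54 ± 0.38. Extracellular matrix genes rose in 20 of 21 cases and recruited monocyte markers in 10 of 10 (adjusted p = 4.97e-18 and 2.51e-09, and each adjusted p = 0.0235 with an estimated correlation).

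In the same comparison Wnt and beta-catenin targets fell in 9 of 16 cases and rose in 1 (adjusted p = 0.000517, and adjusted p = 0.193 with an estimated correlation). Glul fell by 1.55 and Slc1a2 by 3.24. Bile acid genes fell in 8 of 13 cases and male-biased genes in 8 of 9 (adjusted p = 0.0567 and 0.064 with an estimated correlation).

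The male-biased genes split the transgenic livers at week 20. Hsd3b5 gave signals of 28.8, 12.5 and 14 in replicates 1, 2 and 3 of the basal diet and 6824 and 2441 in replicates 4 and 5, against 13893 ± 4355 (SD, n = 5) in wild-type liver. With peretinoin the signals were 2809, 3474, 17097, 9839 and 284 in replicates 1 to 5. The labels do not give the sex of the mice. The Y-linked genes Eif2s3y (1006 to 2616), Uty (424 to 700) and Kdm5d (166 to 586) gave signals above the array medians of 71.5 to 95.7 in all 34 arrays, and Xist, the X-inactivation RNA of females, gave 31.7 to 121.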
